A study of Sus scrofa with 12 samples.

How the data were processed

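Testis and epididymis of boars of the Banna mini-pig inbred line, an inbred line of small Chinese pigs, were profiled by RNA sequencing. Per the labels, each tissue has 5 short-read libraries, numbered 1 to 5, and the animals were adult and untreated. Each library stands for 1 boar, because the number of an animal recurs in the file headers of both tissues (numbers 21, 23, 25, 27 and 29). The labels give an age of 12 months, whereas the file headers give 12, 12, 11, 17 and 11 months for replicates 1 to 5. Age was therefore not used as a variable. Another 2 samples, long-read libraries each made from a pool of 5 boars, were not analysed here.

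Per the labels' protocols, total RNA was extracted with TRIzol and checked for integrity, poly(A) RNA was enriched with oligo(dT) beads, and cDNA was made with a SMARTer kit, size-selected on a gel and amplified by PCR. Per the submitters' processing notes, the tools used were cutadapt 3.0, STAR and featureCounts of the Subread package, with the pig genome build Sscrofa11.1. The annotation release, the strand setting, the treatment of reads that map to several places and the versions of the last tools are not given in the sources used here. The deposited values are raw read counts per gene, whole numbers without normalization, with the length of each gene per the file headers. All 10 files hold the same 30640 gene rows, of which 3056 had 0 reads in all libraries. Of the rows, 15414 were named by a symbol and 15226 by an Ensembl identifier. A RefSeq gene table of the build Sscrofa11.1 matched 822 of these identifiers to a symbol, and 810 were given it as a name. By symbol, 14583 rows were placed on a chromosome. Coordinates are those of the whole gene in that table, counted from 1. Reads of near-identical copies, such as beta-defensins, histones and ribosomal protein retrocopies, may have been split between rows or left out at counting, so single members of these families are uncertain. The same holds for overlapping and antisense genes.

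Library totals were 19518258, 30211957, 21607938, 18715154 and 24355101 reads for testis replicates 1 to 5 and 19643411, 18264309, 21937263, 17980578 and 20422742 for epididymis replicates 1 to 5. A count of 0 allows 3 reads, or 0.0993 to 0.167 CPM in 1 library, where CPM is the count per 1000000 reads of the library. The counts come from PCR-amplified cDNA without molecular identifiers, so floors and intervals cover counting error only. Before averaging, libraries were compared in pairs. The lowest chi-square per degree of freedom was 10.5 within testis and 81.6 within epididymis, and 0 pairs were identical, so each library counts as 1 replicate.

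The tissues were compared with R 4.3.3 and edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 17225 genes, and libraries were scaled with TMM factors. The quasi-likelihood test with robust dispersion and tissue as the only term gave log2 fold changes (testis over epididymis) and p-values, adjusted by the Benjamini-Hochberg method. Standard errors are approximate, since the test gives none. Each was derived as the log2 fold change before edgeR's shrinkage, divided by the square root of the test's F statistic. The fold changes printed beside them are those after shrinkage. Genes past an adjusted p of 0.05 were called. A second test in the same fit, glmTreat, asked for a change beyond 2-fold. Means and SDs of single genes are CPM over the library total. Where a tissue had 0 reads of a gene, the fold change is given against 3 reads over the whole tissue as a lower bound, and with 1 to 3 reads as a ratio with its 95% counting interval.

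Gene lists were written before the data were examined, 27 with at least 5 tested members. They describe spermatogonia, meiosis, haploid germ cells, the piRNA pathway, Sertoli cells, Leydig cells and steroid synthesis, cholesterol synthesis, cell division, epididymal secreted proteins, beta-defensins, ion and water transport, clear cells, basal cells, epithelial cells, duct developmental regulators, steroid receptors and reductases, antioxidant enzymes, smooth muscle and peritubular cells, fibroblasts and matrix, endothelial cells, macrophages, lymphocytes, antigen presentation, red blood cells, adipocytes, the response to tissue handling and ribosomal proteins. They were tested with camera of limma 3.58.1, which compares a list with all other genes, with a preset correlation between genes of 0.01, and again with the correlation estimated per list. fry, which asks whether a list moves in 1 direction at all, was run beside it. All were adjusted over the 27 lists. For each list, members called are counted over all genes tested and adjusted over the list alone. After the results were seen, an exact two-sided permutation test of the mean log2 CPM of each list per library (prior count 2) was added, whose smallest p for 5 against 5 libraries is 0.007937. It treats the libraries as independent, although both tissues come from the same boars. The same test with labels exchanged only within boars was therefore added for list levels, detected genes and the share of the 100 most abundant genes, where 5 boars allow no p under 0.0625.

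Genes named in the text followed a rule set before the data were examined. Per direction it takes the 6 genes of highest mean CPM and the 3 of largest fold. For these picks the rule admits genes with a symbol that passed the 2-fold test and whose libraries did not overlap between the tissues. It leaves out mitochondrial genes there. From each list it takes the 2 members of highest mean CPM and, where called members went both ways, the most abundant one against the majority. It adds the 3 most abundant called genes among X-linked genes, long non-coding genes and genes that differed between boars. The restricted genes, the genes that stood apart in 1 library, and the list members EGR3 and RPL10A were picked after the data were examined. A few genes that the rule takes are not reported here. The 2 sets of RNAs without a poly(A) tail (211 rows of small structural RNAs and 15 of replication-dependent histones, by symbol) were also defined afterwards.

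Descriptive measures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They are the genes at 1 CPM or more, the genes at 5 reads or more after thinning every library to 17980578 reads, the share of reads in the 100 most abundant genes, and the genes restricted to a tissue (at least 1 CPM in all of its libraries and under 0.1 CPM, or 1.80 to 3.02 reads, in each library of the other). They were compared with exact two-sided permutation tests. X-linked genes were compared with autosomal genes by median fold change and camera, and long non-coding with protein-coding genes by Fisher's exact test. The biological coefficient of variation was estimated with edgeR within each tissue.

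The replicate numbers pair the samples, since the file headers give both tissues of a number the same animal. The deviations from the tissue means of samples with the same number had correlations of 0.00867 to 0.0893 across genes. A fit with the replicate number as a block, and a test of its terms for differences between boars, were run as well. Other alternatives were DESeq2 1.42.0 and its size factors, upper-quartile factors, no composition factors, no filter or a filter of 10 reads in every library of a tissue, limma voom, other thresholds for restricted and detected genes, and leaving out each library in turn. After the data were seen, 3 further fits were added, namely testis replicate 4 as the only testis library, where the spread comes from the epididymis libraries alone, epididymis replicates 3 and 4 left out, and the structural RNA and histone rows removed. In simulated data with 200 changed genes among the 17225, the tissue test recovered 6% of 2-fold, 74% of 4-fold, 98.0% of 8-fold and 98% of 16-fold changes and called 6 of 16848 unchanged genes. In the real data 74.4% of genes were called, which loosens the adjusted threshold, so the shares recovered do not apply there. The boar test recovered 78% of 8-fold changes and called 12 unchanged genes, and camera called 1 list, the one that was changed. The simulated genes were drawn independently of each other, so this cannot show how camera behaves with correlated genes.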

Results

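The transcriptomes of the testis, where sperm form and steroid hormones are made, and of the epididymis, the duct in which sperm mature and are stored, were compared in inbred Banna mini-pig boars. Raw read counts per gene were available for 5 testis and 5 epididymis libraries, with 18715154 to 30211957 reads per testis library and 17980578 to 21937263 per epididymis library. Log2 values of the count per 1000000 reads (CPM) correlated across genes at 0.97 to 0.996 within testis, 0.937 to 0.99 within epididymis and 0.757 to 0.805 between the tissues. The p-values of the main edgeR fit measure the spread between the 5 libraries of each tissue, 1 per boar, without use of the pairs. Differences in library content enter this spread too. The p-values of camera, which compares a list with other genes, and of Fisher's test rest on genes as units.

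The libraries of a tissue differed in the kinds of RNA they held. Small structural RNAs, which carry no poly(A) tail, made up 15044 to 16186 CPM in testis replicates 1, 2, 3 and 5, but 71.3 CPM in testis replicate 4 and 72.9 to 134 CPM in the epididymis. The signal recognition particle RNA (row Metazoa_SRP) stood at 7888 to 9134 CPM in those 4 testis libraries and at 7.75 CPM in replicate 4. Replication-dependent histone genes, whose mRNAs also lack a poly(A) tail, summed to 2170 to 3099 CPM, against 77.4 CPM in testis replicate 4 and 64.0 to 299 CPM in the epididymis. Testis replicate 4 is thus the only testis library with the RNA classes of the epididymis libraries, and its value is given beside results that move with it. Comparisons with it as the only testis library take their spread from the epididymis libraries alone, so a call lost or gained there is weak evidence. Genes of the mitochondrial genome took 5238 to 8323 CPM in the other 4 testis libraries, 16159 CPM in replicate 4 and 17840 to 64534 CPM in the epididymis. Epididymis replicate 3 differed most from the others of its tissue, with 585 genes at least 4-fold above each of them, against 5 to 129 for any other epididymis library.

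**Figure D1:**
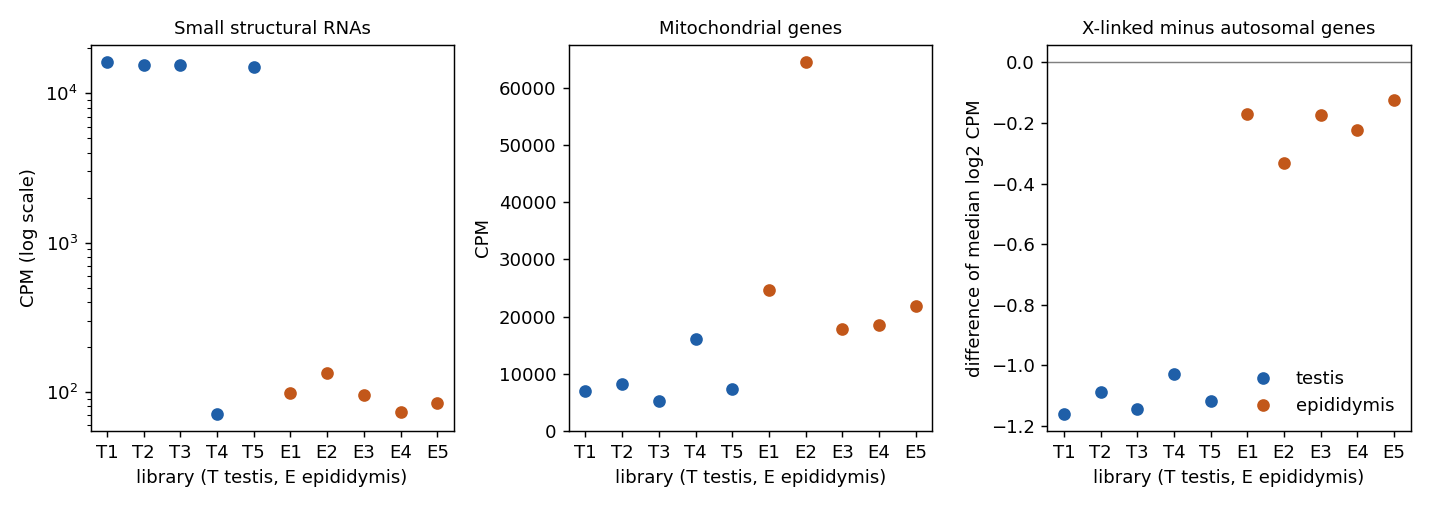
Each point is 1 library, T for testis and E for epididymis with the replicate number. The panels show the CPM of small structural RNAs on a log axis (71.3 in testis replicate 4 and at least 15044 in the other testis libraries), the CPM of mitochondrial genes, and the median log2 CPM of X-linked minus autosomal genes, which lies between -1.16 and -1.03 in testis and between -0.33 and -0.12 in epididymis.

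Testis and epididymis differed in most genes. CYP17A1, INSL3 and PRM1 were among the 6 most abundant genes with a symbol higher in testis, taken past the 2-fold test and without overlap of libraries. Mitochondrial genes were left out of this ranking. CYP17A1, the enzyme that turns progestogens into androgens (chromosome 14, 113805616 to 113820445), had 6549 ± 1558 CPM in testis and 4.47 ± 1.08 in epididymis (SD, n = 5 each), a 1498-fold difference. INSL3, a peptide hormone of Leydig cells (chromosome 2, 59929591 to 59931220), had 5343 ± 1445 against 5.09 ± 1.76 CPM. PRM1, the protamine that packs DNA in sperm heads (chromosome 3, 31861087 to 31861529), had 7809 ± 262 against 74.3 ± 121 CPM. With mitochondrial genes left out, NPC2 was the most abundant gene with a symbol higher in epididymis past the 2-fold test without overlap of libraries. This secreted sterol-binding protein (chromosome 7, 97730532 to 97740087) had 9127 ± 6160 CPM against 74.4 ± 31.4 in testis. Lactoferrin, LTF (chromosome 13, 29413886 to 29445751), had 3988 ± 2103 CPM in epididymis against 0.362 ± 0.141 in testis, a 10750-fold difference.

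The log2 fold changes of these genes, testis over epididymis, were 10.55 ± 0.36 (SE) for CYP17A1, 10.07 ± 0.43 for INSL3, 6.78 ± 1.01 for PRM1, -6.89 ± 0.56 for NPC2 and -13.39 ± 0.83 for LTF, each with all 5 libraries of a tissue above all 5 of the other. Their edgeR quasi-likelihood adjusted p-values were 9.6e-09, 1.3e-08, 7.2e-05, 6.0e-07 and 8.8e-08. The others of the 6 in testis were DHRS4, a retinoid dehydrogenase (chromosome 7, 75242121 to 75255594), with 8643 ± 1306 CPM against 90.1 ± 39.6, A2M, the protease inhibitor alpha-2-macroglobulin (chromosome 5, 62406928 to 62483690), with 7305 ± 1493 against 113 ± 49.9, and SULT1C3, a sulfotransferase, with 6315 ± 2166 against 105 ± 31.3. On the epididymis side stood EPPIN, a protease inhibitor that binds sperm, with 3440 ± 1793 CPM against 18.8 ± 4.84, PTI (chromosome 17, 47773060 to 47780746) with 3497 ± 2176 against 0.391 ± 0.272, ITM2B, a membrane protein (chromosome 11, 19349088 to 19377931), with 4670 ± 1894 against 229 ± 96.0, and EEF1A1, a translation elongation factor (chromosome 1, 92421235 to 92425053), with 4989 ± 1107 against 1254 ± 564. PTI stood at 14.1 CPM in epididymis replicate 3 and at 2947 to 5672 in the others. EEF1A1 reached 2231 CPM in testis replicate 4 and lost its call with that library as the only testis library (log2 -1.05, against -1.97 with all libraries, edgeR adjusted p = 0.103). PTI lost its call there too (edgeR adjusted p = 0.0514), although its log2 difference stayed at -11.9, against -13.15 with all libraries.

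**Figure D2:**
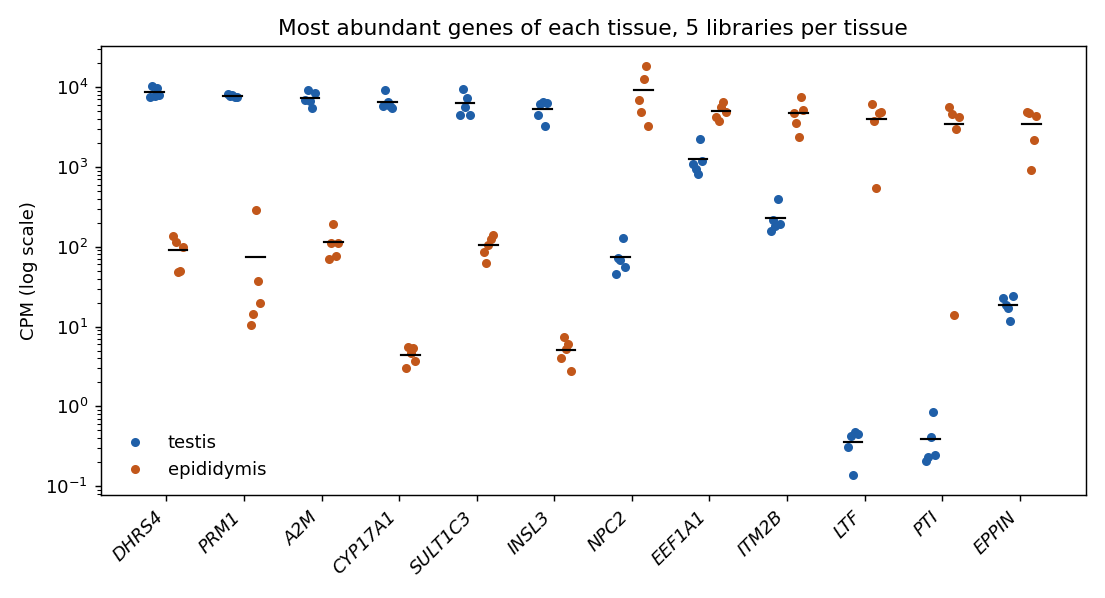
CPM, on a log axis, of the 6 most abundant genes with a symbol per direction past the 2-fold test, with mitochondrial genes left out. Each library is 1 point, and a black bar marks the mean of the 5 libraries. CYP17A1 lies at 5409 to 9242 in testis and 3.05 to 5.53 in epididymis, and LTF at 547 to 6132 in epididymis and 0.139 to 0.481 in testis.

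The largest folds among genes with a symbol belonged to genes that were nearly silent in the other tissue. CPN2, a subunit of the plasma carboxypeptidase N (chromosome 13, 131327508 to 131337721), had 65.3 ± 17.9 CPM in testis and 0 reads in the epididymis, at least 2167-fold higher. CYP11A1, which makes pregnenolone from cholesterol in the first step of steroid synthesis (chromosome 7, 59172829 to 59188479), had 1823 ± 524 against 0.803 ± 0.358 CPM. CRISP1, a cysteine-rich protein that coats maturing sperm (chromosome 7, 43883536 to 43911877), had 1569 ± 970 CPM in the epididymis and 0 reads in testis, at least 57942-fold higher. DEFB128, a beta-defensin (chromosome 17, 34948185 to 34965455), had 30.8 to 11667 CPM in the epididymis and 1 read in testis, a ratio of 314060 with a 95% counting interval of 56366 to 12405000. This ratio rests mainly on epididymis replicate 3, since the others held at most 496 CPM, a spread that the interval does not cover. SPINK14, of a family of protease inhibitors (chromosome 2, 149414615 to 149423473), had 3210 ± 2040 CPM and 2 reads, a ratio of 179970 (49821 to 1486100). The core histone gene H2AC1 had 1219 to 1876 CPM in testis replicates 1, 2, 3 and 5, 0.801 in replicate 4 and at most 0.182 in the epididymis. With testis replicate 4 alone the log2 difference was 3.98 for H2AC1, against 14.42 with all libraries (edgeR adjusted p = 0.0710), and -18.49 for DEFB128, against -17.30 (edgeR adjusted p = 0.101).

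Of 17225 genes tested, edgeR's quasi-likelihood test called 6308 higher in testis and 6506 higher in epididymis, 74.4% in all. A change beyond 2-fold was called for 4703 and 4033 genes. All 5 testis libraries lay above all 5 epididymis libraries in 5529 genes and below them in 5041, where chance gives 0.794% of genes for both directions together. With testis replicate 4 as the only testis library, fewer genes were called, above all fewer of those higher in epididymis. That fit tested 18896 genes, against 17225 with all libraries, so the numbers of calls are not like for like. Its median log2 fold change over all tested genes was -0.19, against -0.07 with all libraries. Testis replicate 4 lay above every epididymis library in 4583 (97.4%) of the 4703 genes and below every one in 3824 (94.8%) of the 4033. It was itself 1 of the 5 testis libraries by which these genes were called, so part of these shares is built in. In that comparison of 1 library against 5, of the genes taken by the naming rule 47 kept their direction and call or lack of one, 35 kept the direction without the call and 3 changed direction. Without epididymis replicates 3 and 4 the tests called 7217 and 6555 genes, and 5555 and 4214 beyond 2-fold.

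Most genes of 3 germ cell lists were higher in testis, although against all other genes only the meiosis list kept its call with an estimated correlation between genes, and the haploid and piRNA lists lost it. Of 31 tested meiosis genes, 28 were higher in testis and 1 in epididymis (28 and 1 adjusted over the list alone), with a median log2 fold change of 4.86. STAG3, a cohesin subunit of meiotic chromosomes, had 889 ± 244 CPM against 2.03 ± 1.27, and REC8, its meiotic partner, 158 ± 26.4 against 7.34 ± 5.53. MSH4, a meiotic recombination protein, went the other way, with 17.5 ± 4.56 CPM in testis and 33.1 ± 5.37 in epididymis (log2 -0.90 ± 0.20, edgeR adjusted p = 0.00132), a call that was lost with testis replicate 4 alone (log2 -0.31, edgeR adjusted p = 0.515). Of 46 genes of haploid germ cells, spermatids and sperm, 45 were higher in testis, also 45 adjusted over the list alone, with a median of 6.50, or 7.69 without epididymis replicate 3. Among them OAZ3, an antizyme of spermatids, had 1935 ± 584 CPM against 8.67 ± 12.3. Of 19 piRNA pathway genes, which silence transposons in germ cells, 18 were higher in testis (18 adjusted over the list alone, median 6.12), such as GTSF1 with 190 ± 51.8 against 2.59 ± 1.24 CPM and DDX4, the germ cell helicase VASA, with 148 ± 47.4 against 1.52 ± 1.11. In epididymis replicate 3 the haploid list lay above the other epididymis libraries by a median log2 of 1.94 and the piRNA list by 1.07, with PRM1 at 290 CPM against 10.5 to 37.0.

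Cell division genes were higher in testis in 18 of 22 cases (18 adjusted over the list alone), with a median log2 fold change of 1.68. PLK1, a mitotic kinase, had 390 ± 68.4 CPM against 6.61 ± 3.10, and MCM7, of the replication helicase, 191 ± 31.2 against 90.7 ± 19.0. Spermatogonial genes went both ways. Of 12 tested, 6 were higher in testis and 4 in epididymis (6 and 5 adjusted over the list alone), with a median of 0.76, or 1.75 without the filter. ETV5, a transcription factor of spermatogonial stem cells, had 124 ± 30.1 against 74.2 ± 30.3 CPM (log2 0.78 ± 0.28, edgeR adjusted p = 0.0254), with 72.9 CPM in testis replicate 4, which alone gave a log2 difference of 0.09 (edgeR adjusted p = 0.903). This call was also lost without testis replicate 2 or epididymis replicate 2 or 5 (edgeR adjusted p = 0.0502 to 0.0633). ID4, an inhibitor of differentiation, was higher in epididymis, with 107 ± 39.1 against 4.05 ± 3.47 CPM.

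Somatic testis cells were represented by Leydig and Sertoli cell genes. Of 17 genes of Leydig cells and steroid synthesis, 14 were higher in testis and 3 in epididymis, both also adjusted over the list alone, with a median log2 fold change of 5.82. CYP17A1 and INSL3 are its most abundant members. HSD11B1, which regenerates active glucocorticoid, was among the 3, with 8.46 ± 2.19 CPM in testis and 31.2 ± 38.1 in epididymis (log2 -1.84 ± 0.59, edgeR adjusted p = 0.0142). Epididymis replicate 3 held 98.8 CPM of it against 10.2 to 22.1 in the others, and the call was lost without epididymis replicates 3 and 4 (edgeR adjusted p = 0.0744). Of 15 Sertoli cell genes, 10 were higher in testis and 1 in epididymis (10 and 1 adjusted over the list alone, median 1.25, or 1.89 without epididymis replicate 3). Their most abundant members were less clear. TJP1, a tight junction protein, had 180 ± 6.98 against 123 ± 45.2 CPM (log2 0.58 ± 0.23, edgeR adjusted p = 0.0385), and leaving out single libraries ended this call for 8 of the 10, with edgeR adjusted p-values of 0.0504 to 0.0975. It also ended without composition factors (0.0566). CITED1, a transcriptional coactivator, had 256 ± 50.9 against 447 ± 445 CPM (edgeR adjusted p = 0.25), with 66.6 to 1149 CPM among epididymis libraries, and it was called higher in epididymis without replicates 3 and 4 of that tissue (edgeR adjusted p = 0.00252). SOX8, a transcription factor, was higher in epididymis at low levels, 2.25 ± 0.90 against 0.571 ± 0.220 CPM.

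Against all other genes, limma's camera with the preset correlation placed 6 lists higher in testis, with adjusted p-values of 9.2e-15 for haploid germ cells, 1.8e-07 for meiosis, 2.5e-07 for the piRNA pathway, 0.000431 for Leydig cells and for cell division, and 0.0225 for Sertoli cells. With an estimated correlation the meiosis list held (limma camera adjusted p = 0.0132). The others were lost, with adjusted p = 0.193 with an estimated correlation for haploid germ cells, 0.125 for the piRNA pathway, 0.0853 for Leydig cells, 0.336 for cell division and 0.280 for Sertoli cells. In an exact permutation test of the list level per library, added after these results were seen, all 5 testis libraries lay above all 5 epididymis libraries for each of these 6 lists (exact p = 0.007937, the smallest possible, 0.0102 adjusted over the lists). With labels exchanged only within boars the exact p was 0.0625 for each, the smallest possible and not a call. Cholesterol synthesis genes, which feed steroid synthesis, were higher in testis in 9 of 20 cases and lower in 3 (9 and 3 adjusted over the list alone), with a median of 0.53 and a limma camera adjusted p of 0.241. The list's median log2 difference from the epididymis was 1.03 in testis replicate 4 and 0.32 in the other testis libraries. LSS, lanosterol synthase, had 329 ± 72.4 CPM in testis against 243 ± 58.8 (log2 0.45 ± 0.22, edgeR adjusted p = 0.0847, but 0.0398 with DESeq2 size factors, 0.0353 without testis replicate 1 and 0.0486 without epididymis replicate 2), and SC5D, a desaturase, 32.9 ± 19.0 against 126.2 ± 71.9.

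Most genes of the secretory, epithelial and stromal lists were higher in epididymis, although with an estimated correlation only secreted proteins and duct regulators kept their call against all other genes, and beta-defensins, epithelial cells, basal cells, smooth muscle and fibroblasts lost it. Of 29 tested genes of epididymal secreted proteins, 26 were higher in epididymis and 0 in testis (26 and 0 adjusted over the list alone), with a median log2 fold change of -8.41, which is also the median with the 2 members without reads in testis at their bound. The median was -7.135 without epididymis replicate 3, -6.12 without replicates 3 and 4 and -6.74 with the boar as a block. CLU, clusterin, the most abundant member with NPC2, was not called, with 2500 ± 492 CPM in testis and 7061 ± 7294 in epididymis (log2 -1.45 ± 0.75, edgeR adjusted p = 0.0981). It had 213 CPM in epididymis replicate 5 and 3744 to 19006 in the others, and without replicate 5 it was called (log2 -1.79, edgeR adjusted p = 0.00479). Of 13 beta-defensins, antimicrobial peptides of epithelia, 10 were higher in epididymis and 1 in testis (10 and 1 adjusted over the list alone), with a median of -12.36, or -10.35 with the 7 members without reads in testis at their bound. Without epididymis replicate 3 it was -10.71. DEFB136 had 846 ± 562 CPM in epididymis against 0.0915 ± 0.0437, with 0.729 CPM in replicate 3. The exception, DEFB123, had 20.6 ± 5.97 CPM in testis and 2.24 ± 4.89 in epididymis (log2 3.25 ± 1.32, edgeR adjusted p = 0.0416), a call that was lost without any single library except epididymis replicate 3 (edgeR adjusted p = 0.0567 to 0.0751) and without the filter (0.0946), although the log2 difference stayed at 2.90 to 3.37 and at 3.25. DESeq2 did not call it either (log2 3.43, adjusted p = 0.0799). Without epididymis replicate 3 it was 8.45, and 6.51 with the boar as a block. In replicate 3 the beta-defensins lay a median log2 of 3.48 above the other epididymis libraries.

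Of 23 epithelial genes, 22 were higher in epididymis (22 adjusted over the list alone, median -6.22), led by PROM2, a prominin of epithelial membranes, with 703 ± 542 against 2.36 ± 0.51 CPM, and EPCAM, an adhesion molecule, with 577 ± 103 against 10.1 ± 6.49. PROM2 stood at 5.15 CPM in epididymis replicate 3. Of 9 basal cell genes, 7 were higher in epididymis (7 adjusted over the list alone, median -5.63), including the keratin KRT14 with 610 ± 287 against 4.67 ± 0.65 CPM. Of 15 developmental regulators of the duct, 13 were higher in epididymis (14 adjusted over the list alone, median -4.62). PAX2, a transcription factor of the Wolffian duct, had 550 ± 279 against 0.25 ± 0.195 CPM, and HOXD8 203 ± 166 against 21.2 ± 5.40. All 14 smooth muscle genes were higher in epididymis (14 adjusted over the list alone, median -4.71), such as the myosin heavy chain MYH11 with 3388 ± 1376 against 107 ± 21.2 CPM and the actin ACTA2 with 2510 ± 830 against 96.4 ± 22.6. Of 17 genes of fibroblasts and matrix, 14 were higher in epididymis (14 adjusted over the list alone, median -2.08). COL1A1, a collagen chain, had 1004 ± 661 against 191 ± 113 CPM, while SPARC, a matrix glycoprotein, had 637 ± 236 against 511 ± 117 (log2 -0.30 ± 0.30, edgeR adjusted p = 0.376). In testis replicate 4 the fibroblast list lay a median log2 of -0.87 from the other testis libraries.

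Limma camera adjusted p-values for these lists with the preset correlation were 2.3e-06 for secreted proteins, 0.0140 for beta-defensins, 3.6e-09 for epithelial cells, 0.00446 for basal cells, 0.000116 for duct regulators, 8.0e-07 for smooth muscle and 0.00105 for fibroblasts. Secreted proteins (limma camera adjusted p = 0.0132) and duct regulators (0.0199) held with an estimated correlation. The others were lost, with adjusted p = 0.280 with an estimated correlation for beta-defensins and for smooth muscle, 0.0853 for epithelial cells, 0.230 for basal cells and 0.336 for fibroblasts. Beta-defensins also lost the call with testis replicate 4 as the only testis library (limma camera adjusted p = 0.0723), although their median stayed at -12.43. The list level of all 5 epididymis libraries lay above that of all 5 testis libraries for each of these 7 lists (exact permutation p = 0.007937, and 0.0625, the smallest possible, within boars).

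Transport and steroid response genes of the epididymis went both ways. Of 18 genes of ion and water transport, 8 were higher in epididymis and 4 in testis (7 and 4 adjusted over the list alone, median -0.17, limma camera adjusted p = 0.615). SLC9A3, a sodium-proton exchanger, had 222 ± 204 CPM in epididymis against 0.896 ± 0.481, and KCNQ1, a potassium channel, 364 ± 42.1 in testis against 16.3 ± 31.0. Of 6 clear cell genes, 3 were higher in epididymis and 1 in testis (3 and 1 adjusted over the list alone, median -1.39, limma camera adjusted p = 0.909). The sign of this median is not settled, since it was 0.44 without epididymis replicate 3 and 0.61 with the boar as a block. The list includes the proton pump subunit ATP6V1C2, with 82.5 ± 42.5 against 0.135 ± 0.151 CPM, the ammonia transporter RHCG, with 40.4 ± 31.5 against 7.81 ± 1.30, a call lost with the boar as a block (log2 -1.76, against -2.39, edgeR adjusted p = 0.0810), and the anion exchanger SLC4A9, with 2.60 ± 2.55 against 17.7 ± 0.48. In epididymis replicate 3 the clear cell list lay a median log2 of 2.51 above the others, although ATP6V1C2 stood at 7.52 CPM there, against 92.8 to 112. Of 10 steroid receptors and reductases, 3 were higher in epididymis and 1 in testis (3 and 1 adjusted over the list alone, limma camera adjusted p = 0.981), with a median of 0.15 and a mean of -0.64. The 5-alpha reductases, which make dihydrotestosterone, differed by isoform. SRD5A1 had 696 ± 236 CPM in testis against 37.4 ± 13.8, and SRD5A2 had 326 ± 514 in epididymis against 0.218 ± 0.079. Of 19 antioxidant enzymes, 8 were higher in testis and 7 in epididymis (8 and 7 adjusted over the list alone), with a median of -0.32 but a mean of 0.20 (limma camera adjusted p = 0.919). GPX4, a peroxidase of sperm mitochondria, had 1787 ± 169 against 501 ± 138 CPM. SOD1, a superoxide dismutase, had 197 ± 147 in testis against 501 ± 243 (log2 -1.36 ± 0.46, edgeR adjusted p = 0.0193), with 458 CPM in testis replicate 4, which alone gave a log2 difference of -0.05 (edgeR adjusted p = 0.966). The SOD1 call was also lost without testis replicate 1, 3 or 5 or epididymis replicate 5 (edgeR adjusted p = 0.0511 to 0.0669).

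Genes of immune cells, vessels, blood and fat showed smaller or mixed differences. All 12 tested genes of antigen presentation were higher in epididymis (12 adjusted over the list alone, median -1.83, limma camera adjusted p = 0.000431, adjusted p = 0.280 with an estimated correlation). CD74, the invariant chain, had 1858 ± 588 against 475 ± 28.3 CPM, and B2M 319 ± 142 against 28.9 ± 5.92. Of 15 macrophage genes, 10 were higher in epididymis and 2 in testis (10 and 2 adjusted over the list alone, median -1.16, limma camera adjusted p = 0.0962, which came to 0.0327 without the filter and 0.0488 without epididymis replicate 5). CD68 had 78.6 ± 47.2 against 4.80 ± 2.14 CPM, C1QC 52.5 ± 40.2 against 32.7 ± 7.35 (edgeR adjusted p = 0.185) and MRC1, the mannose receptor, 6.02 ± 5.77 against 54.7 ± 9.78 in testis. Of 15 lymphocyte genes, 7 were higher in epididymis and 4 in testis (7 and 4 adjusted over the list alone, median -1.01, limma camera adjusted p = 0.490). CD247, a T cell receptor chain, had 98.6 ± 25.3 CPM in testis against 6.33 ± 3.83, and CD4 14.03 ± 4.80 against 2.08 ± 0.99. Of 15 endothelial genes, 7 were higher in epididymis and 1 in testis (7 and 1 adjusted over the list alone, median -0.59, limma camera adjusted p = 0.149). EGFL7 had 483 ± 221 against 49.3 ± 15.6 CPM, VWF 173 ± 85.0 against 192 ± 72.4 (log2 0.19 ± 0.36, edgeR adjusted p = 0.639) and FLT1, a VEGF receptor, 25.2 ± 7.27 against 60.7 ± 8.83 in testis.

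Of 5 red blood cell genes, 3 were higher in epididymis and 1 in testis (3 and 1 adjusted over the list alone, median -1.83, limma camera adjusted p = 0.490). The haemoglobin gene HBB had 27.8 ± 21.1 against 5.78 ± 4.35 CPM, and ALAS2, of haem synthesis, 8.61 ± 6.71 against 2.32 ± 2.02, a call lost without testis replicate 1, 4 or 5 or epididymis replicate 2 or 3 (edgeR adjusted p = 0.0648 to 0.0865) and without epididymis replicates 3 and 4 (0.0527). EPB42 had 1.08 ± 0.26 against 2.16 ± 0.57 in testis and was not called with the boar as a block (edgeR adjusted p = 0.0535). Of 8 adipocyte genes, 3 were higher in epididymis and 1 in testis (2 and 1 adjusted over the list alone), with a median of -0.87 but a mean of 0.11 (limma camera adjusted p = 0.909). This median was 0.24 without epididymis replicate 3, -0.02 with the boar as a block and -1.75 to -1.38 without any single testis library or without epididymis replicate 5, so its direction is not settled. CFD, a serum protease of fat, had 88.0 ± 45.6 against 20.2 ± 5.42 CPM, and LEP, leptin, 48.7 ± 4.63 CPM in testis against 0.333 ± 0.483.

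Immediate-early genes that respond to tissue handling and genes of ribosomal proteins were higher in epididymis. Of 15 handling genes, 12 were higher in epididymis and 2, KLF4 and EGR3, in testis (12 and 2 adjusted over the list alone, median -2.66, limma camera adjusted p = 0.0150, adjusted p = 0.547 with an estimated correlation). EGR1 had 340 ± 277 against 23.8 ± 11.15 CPM, FOS 298 ± 191 against 36.4 ± 15.9, and KLF4, which is also a factor of post-meiotic germ cells and Sertoli cells, 33.7 ± 7.12 against 178 ± 30.1. Of 59 ribosomal protein genes, 55 were higher in epididymis and 2, RPL10A and RPL10L, in testis (55 and 2 adjusted over the list alone, median -1.83, limma camera adjusted p = 2.7e-12, adjusted p = 0.280 with an estimated correlation). RPS2 had 2676 ± 406 against 749 ± 198 CPM. RPLP0, with 2178 ± 366 against 1669 ± 247 (log2 -0.37 ± 0.19, edgeR adjusted p = 0.0936), was called without testis replicate 4 (edgeR adjusted p = 0.0269) or without epididymis replicate 3 (edgeR adjusted p = 0.0424). RPL10L, a retrogene used by germ cells when the X-linked copy is silent, had 105 ± 11.7 CPM in testis against 0.28 ± 0.298. The list's median difference from the epididymis was -1.27 in testis replicate 4 and -2.02 in the other testis libraries. For the handling list these medians were -2.17 and -2.73. Over all 27 lists, camera placed 6 higher in testis and 10 in epididymis with the preset correlation, but 1 and 2 with an estimated one, and 17 of 100 splits of the libraries, the real one included, called at least 16 lists with the preset one. The exact test per library separated the tissues for 9 lists higher in testis and 12 higher in epididymis, with overlap for 6, although within boars no exact p could fall under 0.0625. It does not compare a list with other genes, and many single genes separated the tissues too (5529 and 5041 of 17225). The 9 include spermatogonia, cholesterol synthesis and antioxidant enzymes, and the 12 ion and water transport and clear cells, none of which camera called. fry called 21 lists.

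**Figure D3:**
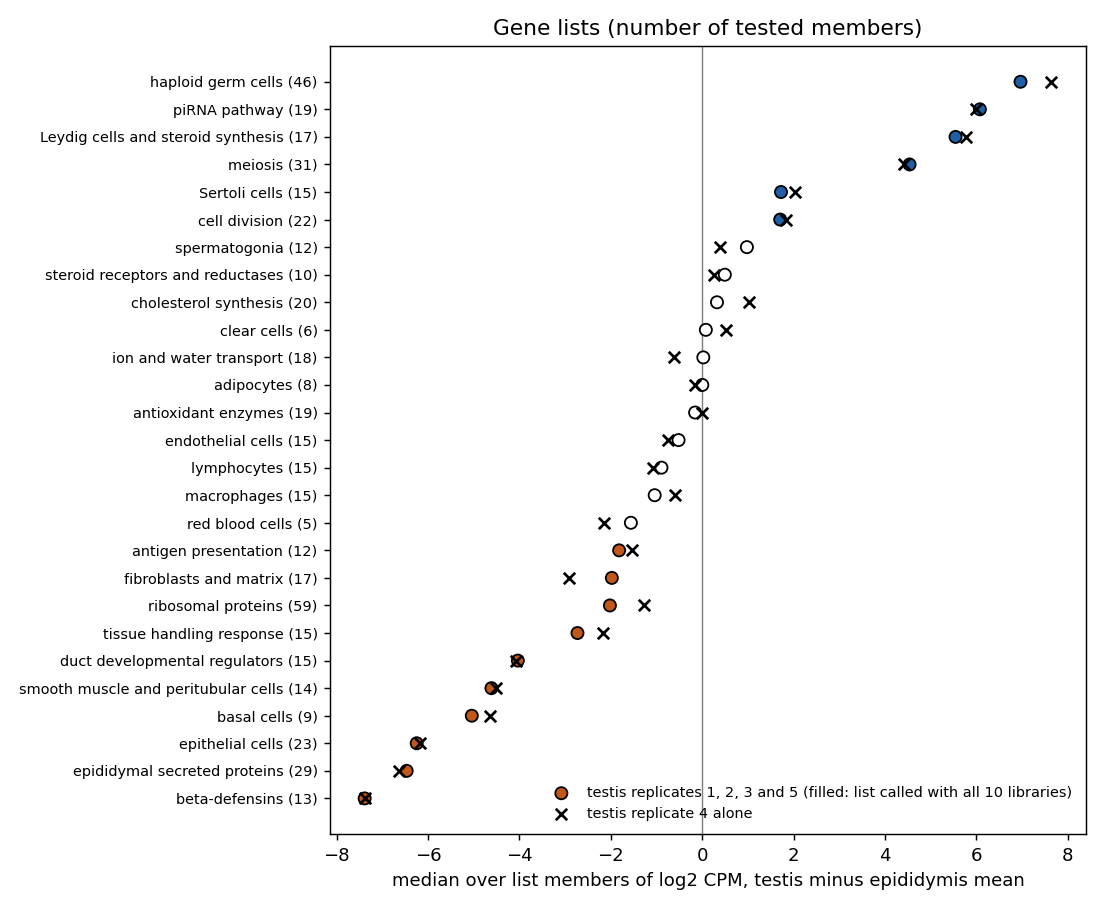
Each line is 1 of the 27 gene lists with its number of tested members, and the axis is the median over members of log2 CPM in testis minus the epididymis mean. Circles are testis replicates 1, 2, 3 and 5 and crosses are testis replicate 4 alone, with filled circles for lists called by camera with the preset correlation (blue higher in testis, orange higher in epididymis). Haploid germ cells lie at 6.97 and 7.64, and ribosomal proteins at -2.02 and -1.27.

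Genes on the X chromosome, which is silenced in male meiosis, were lower in testis. Of 426 tested X-linked genes, 61 (14.3%) were higher in testis and 260 (61.0%) in epididymis, against 33.8% and 39.4% of 12351 autosomal genes. The median log2 fold change was -1.25 for X-linked and -0.17 for autosomal genes, a difference of -1.08 (limma camera p = 1.4e-05, and 0.000918 with an estimated correlation), while medians of single autosomes lay between -0.43 and 0.11. With testis replicate 4 as the only testis library the difference was -0.98. The most abundant called genes were FLNA, an actin crosslinker (chromosome X, 124889934 to 124915000), with 280 ± 121 CPM in testis against 2512 ± 513, RPL10 (chromosome X, 124927249 to 124929791), with 248 ± 51.2 against 2162 ± 221, and RPS4X (chromosome X, 58149302 to 58155179), with 581 ± 292 against 1828 ± 512. RPL10 and RPS4X are ribosomal protein genes too, and RPS4X was not called with testis replicate 4 alone (log2 -0.65, against -1.65 with all libraries, edgeR adjusted p = 0.338). Another 4433 tested genes had no chromosome.

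The testis expressed more genes than the epididymis, and its reads were less concentrated. After thinning to equal depth, 18721 ± 536 genes had at least 5 reads in testis and 16828 ± 454 in epididymis (SD, n = 5 each, exact permutation p = 0.007937, the smallest possible), with 17775 in testis replicate 4. Exchanging the labels only within boars cannot give an exact p under 0.0625, which was reached for all 3 measures of this part, so that test alone calls none of them. At 1 CPM or more there were 15599 ± 200 and 14318 ± 400 genes (exact permutation p = 0.007937, n = 5). The 100 most abundant genes took 20.5 ± 1.45% of reads in testis and 25.5 ± 2.12% in epididymis (exact permutation p = 0.007937, n = 5). By the rule of at least 1 CPM against under 0.1 CPM, 279 genes were restricted to testis, 72 of them with a symbol, and 52 to epididymis, 32 with a symbol. Among those with a symbol, the most abundant in testis included CPN2 and AQP8, a water and ammonia channel, at 38.0 ± 7.43 CPM. In the epididymis the most abundant with a symbol were SPINK14, DEFB128, WFDC10A, of the whey acidic protein family, at 1602 ± 927 CPM, and CRISP1. The numbers depend on the limit, with 960 and 273 genes at under 0.5 CPM in the other tissue and 90 and 26 at 0 reads. Without epididymis replicate 3 the testis number was 421, and with testis replicate 4 as the only testis library the epididymis number was 127.

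Rows without a symbol were more often higher in testis. Of 3404 such genes tested, 49.2% were higher in testis and 28.7% in epididymis, against 33.1% and 40.2% of 12884 protein-coding genes (Fisher's exact p = 2.8e-65, across genes, which are not independent replicates). How these shares move with testis replicate 4 was not examined. Structural RNAs and histones were set apart by symbol only, so rows without a symbol may hold such RNAs. Of 45 genes matched by symbol to a long non-coding RNA, 13 were higher in testis and 14 in epididymis (Fisher's exact p = 0.635 for 28.9% against 33.1% higher in testis). The most abundant of these, GSN, ISYNA1 and HNRNPU, carry the symbols of known protein-coding genes, so this class is unreliable. GSN, gelsolin, had 261 ± 37.4 CPM in testis against 1531 ± 697, ISYNA1, of inositol synthesis, 1354 ± 151 against 303 ± 194, and HNRNPU, a nuclear RNA-binding protein, 204 ± 133 against 353 ± 62.0. HNRNPU (log2 -0.78 ± 0.32, edgeR adjusted p = 0.0455) reached 441 CPM in testis replicate 4, and its call was lost with DESeq2 size factors (edgeR adjusted p = 0.0928), without composition factors (0.0525), without the filter (0.0548), without structural RNA and histone rows (0.0670), in DESeq2 (0.0845) and without any single library except testis replicate 4.

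Differences between boars shared by both tissues were not shown. With tissue and boar in the edgeR model, 3 of 17225 genes differed between boars at an adjusted p under 0.05 and 518 at an unadjusted p under 0.05, fewer than chance alone would give. The test called 12 unchanged genes in simulated data, so the 3 calls are weak, and each was expressed in essentially 1 tissue. DEFB128 (edgeR adjusted p = 0.00432) had 11670 CPM in epididymis replicate 3, the matrix protease MMP7 (edgeR adjusted p = 0.0303) had 584 CPM in epididymis replicate 2 and 3.83 in replicate 3, and the small Cajal body RNA SCARNA10 (edgeR adjusted p = 0.0303) had 0 reads in testis replicate 4 and 232 to 282 CPM in the other testis libraries. Without 1 boar the test called 0 or 1 genes, and 25 without the filter. The biological coefficient of variation between boars was 0.285 in testis and 0.52 in epididymis. It was 0.136 without testis replicate 4 and 0.409 without epididymis replicate 3.

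The epididymis libraries differed strongly in single genes, which were picked here after the values were seen. Epididymis replicate 3 was high in TEDDM1 (8947 CPM against 2.28 to 5.73), RNASE10 (5909 against 6.12 to 16.02), the peroxidase GPX5 (2577 against 1.56 to 52.7), OVCH2 (1938 against at most 0.329) and the receptor kinase ROS1 (529 against 1.37 to 16.2), and low in CES5A, a secreted esterase (6.11 against 1425 to 5415), CRISP1 (53.2 against 1382 to 2680) and PROM2 (5.15 against 455 to 1373). Replicate 4 had 15520 CPM of the mannosidase MAN2B2, against 18.6 to 27.3. The cystatin CST11 was high in replicates 3 and 4 (599 and 382 CPM) and at most 2.35 CPM in the others. Counting genes at least 16-fold above each other library of the tissue, at 20 CPM or more, gave 72 in replicate 3, 7 in replicate 4, 1 in replicate 5 and 0 in replicates 1 and 2. The part of the duct that was sampled is not stated in the labels.

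**Figure D4:**
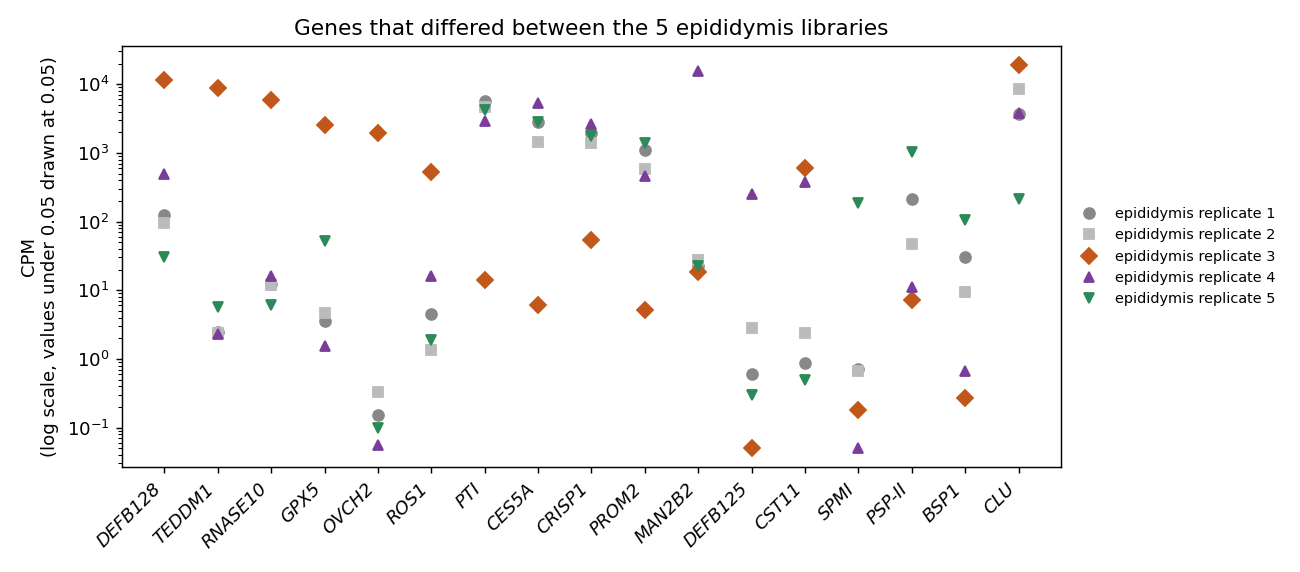
CPM, on a log axis with values under 0.05 drawn at 0.05, of 17 genes that differed between the 5 epididymis libraries, with 1 symbol per library. Replicate 3 lies above the others for DEFB128 to ROS1 and below them for PTI to PROM2, and replicate 4 lies above them for MAN2B2 (15520 against at most 27.3).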

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

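The tests of structural RNAs, of the germ cell mix, of abundant testis genes and of the ribosomal list in testis replicate 4, and all counts over splits except that of lists with an estimated correlation, were chosen only after the result was seen. Each of 235 groups of 5 libraries was searched for 1 library whose gap to the nearest other exceeded 0.71 of the group's range, and 46 groups held one. Chance flags about 1 in 20 groups. Of the 46, 25 were testis replicate 4, 13 epididymis replicate 3, 3 epididymis replicate 2, 2 epididymis replicate 5, and 1 each testis replicates 2 and 3 and epididymis replicate 1.

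Testis replicate 4 stood apart from the other 4 testis libraries in small structural RNAs (71.3 CPM against 15044 to 16186). Of the 4 germ cell and division lists, the lowest median log2 difference from the other testis libraries was -0.19, so none was lost as the structural RNAs were. A smaller shift in the mix of germ cells is not excluded, since the bounds of this test asked for a large loss. Of 30 structural RNA rows at 1 CPM or more, 23 (76.7%) lay more than 4-fold below the lowest other testis library, and 12 of 14 histone rows did too. These rows raised the question themselves, so a library preparation that kept RNAs without a poly(A) tail in testis replicates 1, 2, 3 and 5 cannot be told apart from other causes. The labels describe poly(A) enrichment for every library and name no batch. The boar of this number is 17 months old per the file headers, and an effect of age was not tested.

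Epididymis replicate 3 stood apart in 585 genes at least 4-fold above and 267 at least 4-fold below each other epididymis library. If the germ cell RNA (PRM1 at 290 CPM against 10.5 to 37.0) had come with testis tissue, a share of 3.45% would be needed. Yet DHRS4, A2M, CYP17A1, SULT1C3 and INSL3 stood at a median of 16.3% of the level that this share brings (2.08% to 77.4%). These values include the level of the epididymis itself, which was not subtracted. Only A2M lay above the other epididymis libraries (195 CPM against 69.7 to 113). DHRS4 lay below them, and the other genes lay within their range. This argues against testis tissue. Of the 585 genes, 22.9% had a higher mean in testis, which by itself was too close to the bounds set beforehand to decide. Tissue from another part of the duct cannot be told apart from other causes, since the 8 proximal duct markers had a median log2 difference of 0.82, with LCN9, LCN10, ADAM7 and ADAM28 above each other library and LCN8, ETV4, DUSP6 and SPRY4 not. Germ cells or sperm in the duct may contribute to PRM1 and OAZ3 and were not tested.

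Ribosomal protein genes were lower in testis by a median log2 of -1.83. In testis replicate 4 alone, which shares the RNA classes of the epididymis libraries, the median was -1.27 (quartiles -1.59 and -0.96), and 55 of 59 genes lay below every epididymis library. This rests on 1 library whose preparation is not known to match the epididymis, so the preparation of the other testis libraries cannot be told apart from other causes. Gene length as matched here did not bring a difference of this size. Of 10000 lists matched on length and mean expression, 0% had a median as low (median -0.26, lowest -1.27). Their genes were drawn independently, whereas ribosomal protein genes had an estimated correlation of 0.516, so the spread of these lists is too narrow. Across genes, shorter ones ran higher in testis replicate 4 than in the other testis libraries (Spearman rho -0.15, against -0.061 to 0.054 for each other testis library). A smaller part of length is not excluded. A difference between the tissues themselves stays open and was not tested.

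Other values of testis replicate 4 that stood apart were 17775 genes at 5 reads or more after thinning (others 18819 to 19049) and 16159 mitochondrial CPM (others 5238 to 8323). Its list levels in mean log2 CPM were 8.07 for haploid germ cells (others 7.57 to 7.70), 4.34 for Sertoli cells (4.53 to 4.59), 4.78 for fibroblasts and matrix (5.38 to 5.54) and 7.57 for ribosomal proteins (6.72 to 6.83). It was the highest testis library, in CPM, for EEF1A1 (2231), ITM2B (396), ID4 (10.3), GTSF1 (282), DDX4 (230), SC5D (66.6), EPCAM (21.7), SOD1 (458), CD68 (8.55), KLF4 (230), RPS4X (1095) and HNRNPU (441). It was the lowest for STAG3 (464), OAZ3 (923), PLK1 (271), SLC4A9 (16.8), FLT1 (45.2) and SCARNA10 (0 reads, against 232 to 282 CPM).

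Epididymis replicate 3 was the highest of its tissue, in CPM, for PRM1 (290), OAZ3 (30.5), DEFB128 (11670), HSD11B1 (98.8), DEFB123 (10.99), KCNQ1 (71.8), SLC4A9 (7.07), HOXD8 (494), SRD5A2 (1240) and LEP (1.19), and the lowest for ATP6V1C2 (7.52). Its list levels were 0.66 for the piRNA pathway (others -0.55 to -0.20) and 2.90 for clear cells (others 1.24 to 1.53). Epididymis replicate 2 had 64534 mitochondrial CPM (others 17840 to 24721), 16.9 CPM of REC8 (others 3.33 to 7.18) and 584 CPM of MMP7 (others 3.83 to 164). Epididymis replicate 5 had 253 CPM of SC5D (others 76.2 to 109) and 2704 CPM of RPS4X (others 1397 to 1763). Epididymis replicate 1 had 46.0 CPM of KLF4 (others 28.3 to 33.2), testis replicate 2 had 9242 CPM of CYP17A1 (others 5409 to 6516), and testis replicate 3 had a lymphocyte level of 1.13 (others 0.70 to 0.82).

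In 100 of the possible splits of the 10 libraries into 5 and 5, 1 split, the real one, gave as many called genes as the tissues did, and the highest other called 0 by edgeR. The same held beyond 2-fold (1 split, highest other 0) and for lists with an estimated correlation (1 split with 3 lists, highest other 0). It also held for the X-linked difference (1 split at -1.08, the largest other 0.64 in size). No other split drawn thus reached the real values of these measures. Chance cannot be excluded for the number of lists called with the preset correlation. For that number, 17 splits, the real one included, gave as many as the 16 real ones. Another split gave up to 20 lists, with a median of 12 and a lowest of 7. Every other split drawn holds both tissues in each group, so part of the tissue difference remains in them and also adds to the spread within their groups. These splits therefore cannot exclude chance for the other measures either. Of the splits, 13 part all 5 boars' pairs as the real one does, too few for a share under 0.05, and the highest values among the others were 0 genes, 17 lists and 0.59 for X-linked genes.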

How the results depend on the processing

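The comparisons with testis replicate 4 as the only testis library, without epididymis replicates 3 and 4, and without structural RNA and histone rows, and exact tests within boars, were chosen only after the results were seen. The X-linked difference, detected genes and the share of the 100 most abundant genes kept direction and side of the threshold under every alternative run. So did the absence of a call for long non-coding genes. Excepted are exact tests within boars, which cannot go below 0.0625 for detected genes and the share of the 100 most abundant genes. Which tissue had more called genes was not settled. It was the epididymis with all libraries (6308 in testis and 6506 in epididymis) and with upper-quartile factors or no composition factors. It was the testis in DESeq2, in limma voom, with the boar as a block and without the filter (8632 and 7249). Beyond 2-fold, 4703 and 4033 genes were called with all libraries, and 4414 and 2870 in DESeq2. With testis replicate 4 alone, 2145 genes were higher in epididymis, and 1062 beyond 2-fold. In that fit the spread comes from the epididymis libraries alone and 18896 genes were tested, so its numbers of calls are not like for like. Leaving out single libraries gave 6124 to 6980 genes higher in testis, 6094 to 6883 higher in epididymis and an X-linked difference of -1.11 to -1.07. DESeq2 called 6789 and 6176 genes and limma voom 6518 and 6285. DESeq2 size factors moved the median of all genes by a log2 of 0.13, and 52.4% of calls were then higher in testis. With the boar as a replicate block, 6307 genes were higher in testis and 6055 in epididymis (4741 and 3787 beyond 2-fold), and of the named genes only RHCG and EPB42 lost their call. No other call of a named gene, and no camera call of a list with the preset correlation, changed with this block. Exact tests of list levels within boars could not go below 0.0625 either. List medians whose sign turned, besides those of clear cells and adipocytes, were those of ion and water transport (0.46 without epididymis replicates 3 and 4) and of steroid receptors and reductases (-0.002 with testis replicate 4 alone), 2 lists that were not called. The macrophage median, also of a list not called, came to -0.57 with testis replicate 4 alone and -0.32 without epididymis replicates 3 and 4. With an estimated correlation 1 list was higher in testis and 2 in epididymis, and the cause of the lower number was not tested. Genes restricted to testis were 960 and genes restricted to epididymis 273 under 0.5 CPM in the other tissue, 90 and 26 at 0 reads, and 45 and 21 at 5 CPM or more in the higher tissue, by construction of the limits. Without single libraries they were 285 to 421 and 54 to 77, without epididymis replicates 3 and 4 588 and 86, and with testis replicate 4 alone 127 were restricted to epididymis, since fewer libraries must meet the limit. Genes that differ between boars were 0 to 1 without 1 boar (edgeR, against 518 at an unadjusted p under 0.05 with all boars) and 25 without the filter, where the cause was not tested. The spread between boars was 0.136 to 0.313 in testis and 0.409 to 0.55 in epididymis without single libraries, lowest without testis replicate 4 and epididymis replicate 3, and 0.579 in epididymis without the filter. Of the named genes, VWF (-0.72), RPLP0 (0.0396) and HNRNPU (0.43) changed direction with testis replicate 4 alone and C1QC (0.27) without epididymis replicates 3 and 4, and the cause was not tested. In the other alternatives 80 to 86 named genes kept direction and call. Depth limits the lower bounds of genes with 0 reads in a tissue, which rest on 3 reads.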

Other observations

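All genes in this part were chosen only after their values were seen, with no test beyond the tests of boars. Epididymis replicate 5 held 1016 CPM of PSP-II, a spermadhesin, against 7.20 to 211 in the others, 104 CPM of BSP1, a protein that binds sperm membranes, against 0.274 to 30.04, and 186 CPM of SPMI against at most 0.713. The beta-defensins did not move together. DEFB127 (3731 CPM), DEFB113 (2870) and DEFB128 (11670) peaked in epididymis replicate 3, DEFB125 in replicate 4 (254 against at most 2.85), while DEFB115 (11.6 against 345 to 954) and DEFB136 (0.729 against 696 to 1398) were lowest in replicate 3. Other genes high in replicate 3 were the glutamate transporter SLC1A1 (983 CPM against at most 0.734), PVALB, parvalbumin (983 against at most 0.294) and SERPINF1 (837 against 21.7 to 34.3).

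A gene without a symbol, ENSSSCG00000051428.1, was high in boars 2 and 3 in both tissues, with 421 and 361 CPM in testis against 9.58 to 14.1 in the other boars, and 6.02 and 6.75 CPM in epididymis against 0.612 to 0.713. Another, ENSSSCG00000002529.4, was high in boars 4 and 5 in both tissues, with 8.5 and 8.46 CPM in testis against 1.49 to 2.22 and 22.9 and 20.3 in epididymis against 3.24 to 4.27. Neither passed the edgeR test of boars (adjusted p = 0.128 and 0.204). In a limma test of boars on log2 CPM, run to compare pairings, 0 genes passed an adjusted p of 0.05 (407 at an unadjusted p under 0.05, while edgeR called 3). The real pairing of the tissues gave 10 genes with a boar term at an unadjusted p under 0.001 in it, against at most 9 and a median of 3 in the 44 pairings that match no number.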
